A study of Dunaliella salina with 18 samples.

How the data were processed

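RNA was sequenced from 18 libraries of Dunaliella salina, 3 at each of 0h, 4h and 24h in the H2L and L2H arms. Per the submitters' processing notes, FastQC, Bowtie2 and RSEM were used, with no versions given. The authors deposited 1 table for the series whose values are a signal of abundance scaled for transcript length and library depth; whether the scale is FPKM or TPM is not given in the sources used here. The values are not counts, so no count model was applied. Columns were matched to samples by their titles, and 0 columns belonged to no sample.

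All 43236 transcripts in the table keep distinct identifiers when the last part (_i and a number) is removed, though the first part can be shared. Of them 7 are listed at 0 in all libraries. Transcripts with a value of at least 1 in at least 3 libraries were tested, which left 34166 (79.0%). Values were taken as log2(value + 1) without further normalization, so a log2 change understates the change of low transcripts. Limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 18 libraries with a trend in the prior variance, and p-values were two-sided and adjusted with the Benjamini-Hochberg method. A transcript was called at an adjusted p under 0.05. The median change over tested transcripts was between -0.08 and 0.05 on the log2 scale in every contrast. The groups, the contrasts and their limma test, and all alternatives but the last 3 named below were fixed before the data were examined. The tests of counting noise, library series and shared libraries were written after.

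Transcripts were named by a rule fixed before the data were examined: for each change from 0h and for the comparison of the arms at 0h, the 2 largest rises and 2 largest falls among transcripts called, with a mean of at least 10 in the higher group and no overlap between the groups' libraries. No overlap arises by chance in 10% of transcripts with 3 libraries against 3. The fixed lists of gene families were not tested, because 0 identifiers matched the reference gene table, which describes another strain and carries no identifiers of this assembly. The camera and fry tests planned for those lists were not run.

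Relative depth was sought through low rows, in a way that cannot reveal large differences. Of 32579 low rows, 9391 (28.8%) had values within 0.2 reads of whole multiples of 1 step, and the value of 1 read relative to H2L 0h library 1 was read from 515 or more transcripts per library. Whole reads could not be recovered for most rows, so the absolute depth is unknown and no counting interval is given. The counting error of abundant transcripts was estimated with the value of 1 read in the rows that are whole multiples (99th percentile 0.953). Over all low rows, including those whose lowest value need not be 1 read, that percentile is 138. The estimate for a mean of at least 1000 is then up to 0.739, which would not separate libraries 1 and 2 from counting error. Neither would it separate libraries 1 and 3, whose SD was 0.342 to 0.688 there, so this estimate cannot tell close from distant libraries. With 0.953 libraries 1 and 2 exceeded the estimate in 0 of 6 groups at means of 20 to 50 and of 50 to 100, in 2 at 100 to 300, and in 6 at 300 to 1000 and above; with 138 they exceeded it in 0 of 6 throughout.

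The test was checked on simulated data for the comparison of H2L 4h with 0h. In 5 runs over 34166 transcripts with 200 changed, it recovered 27.2% of changes of 1.5-fold, 72.8% of 2-fold, 96.8% of 4-fold and 100% of 8-fold, and 5.61% of its calls were false. The changed transcripts were drawn only from the more abundant ones, so these shares do not hold for low transcripts. Noise was drawn independently for every library, so the false share does not cover the likeness of libraries 1 and 2. Overlaps between comparisons that share libraries were set beside the overlap of independent lists, and the covariances of their changes beside 20 simulations of unchanged groups. The simulated groups gave 0 shared calls, which says nothing about overlaps among real calls. Their noise was also independent between libraries, so their covariances may be too small where libraries 1 and 2 deviate together. Library measures were compared by exact permutation tests, 25 in all, of which none was under an adjusted p of 0.781.

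Alternatives changed 1 choice at a time. The block was the library number within the arm or, between arms, the set of title tags. Libraries were limited to 1 and 2, left out singly, or limited to the groups compared. Values were taken with quantile normalization, upper-quartile scaling, no filter, a minimum value of 10, or pseudocounts of 0.1 and 5. The fit was run with array weights, no trend, a 2-fold minimum and an adjusted p under 0.01. Averaging libraries 1 and 2, leaving out the third L2H libraries at 0h and 4h, and leaving out libraries of groups outside a comparison were chosen after seeing the data.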

Results

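Transcript abundance was measured by RNA sequencing in the halotolerant green alga Dunaliella salina, strain CCAP 19/3, after reciprocal changes of salinity. The design holds 18 libraries in 6 groups of 3. The arms are called H2L and L2H after the sample titles, and each was sampled at 0h, 4h and 24h. The titles and the condition field of the labels give opposite directions for the salinity change in each arm, so the arms are named here by title and neither is assigned a direction. The table lists 43236 assembled transcripts, each with 1 abundance value per library. It carries identifiers of assembled sequences without gene names, and 0 of them matched the reference gene table, so transcripts are named by identifier.

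The library totals lay between 749880 and 842410 units. The number of reads behind a library is unknown, since the values are scaled for depth, but the value of 1 read, read from steps among low rows relative to H2L 0h library 1, ranged from 0.976 to 1.14. Both values in such a ratio had to lie close to the lowest value of their row, which keeps the ratio near 1 whatever the depth. Whether depth differed is therefore unknown, and transcripts listed at 0 ranged from 3968 to 6626 per library. Libraries 1 and 2 of every group carry the same set of title tags in both arms, and the third library carries a tag set of its own in each arm. Within every set the tag at 24h differs from the tag at 0h and 4h. A change from an earlier time to 24h therefore cannot be told apart from a difference between tags, whose meaning is not stated. Pearson's r across transcripts was 0.963 to 0.969 between libraries 1 and 2 of a group and 0.945 to 0.962 between either of them and the third. The transcripts are not independent replicates, so these r describe likeness only. Of the 18 libraries, 15 were most like a library of their own group. The third L2H libraries at 0h and 4h were most like each other (r = 0.967), and the third H2L library at 0h was most like the third L2H library at 24h (r = 0.949). In transcripts with few reads, libraries 1 and 2 differed by no more than counting noise (chi-square per degree of freedom 0.980 to 1.05, with only L2H 24h under p = 0.05, at 0.037), while pairs with the third library gave 1.10 to 1.24. In the 122 transcripts with a mean of at least 1000 the SD of the log2 ratio of libraries 1 and 2 was 0.0917 to 0.209, and that of libraries 1 and 3 was 0.342 to 0.688. The counting error was up to 0.0613 or up to 0.739, depending on which low rows set the value of 1 read. The larger error could not separate either pair from counting error. Libraries 1 and 2 were kept as separate samples because the series lists 18 biological samples in triplicates, which the spread between them does not test. Because this decision sets the spread, the number of calls in each comparison is given beside the number with libraries 1 and 2 averaged and counted as 1 sample. The labels do not say how the cultures were grown or divided, and p-values measure the spread between these libraries, which may be technical.

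**Figure D1:**
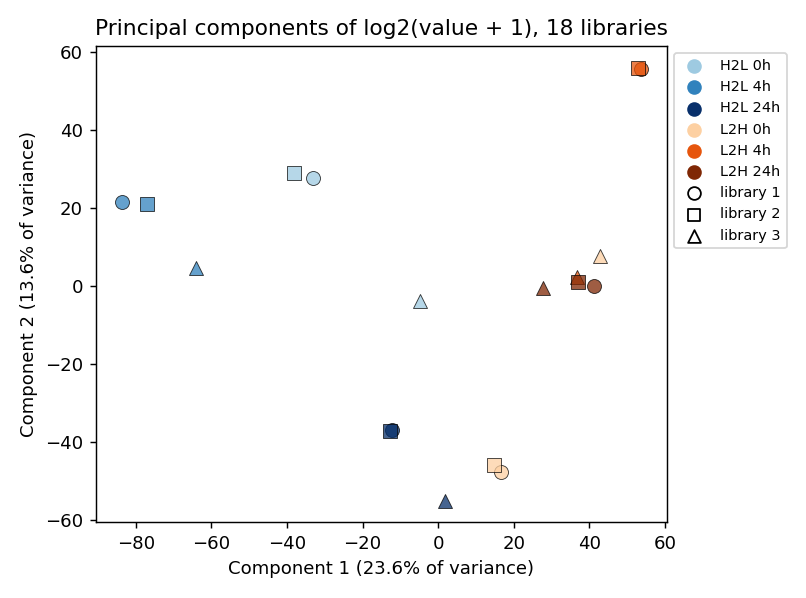
Principal components of log2(value + 1) for the 34166 tested transcripts in 18 libraries, with color for the group and shape for the library number. Component 1 held 23.6% and component 2 held 13.6% of the variance; libraries 1 and 2 of each group lie together, and the third L2H libraries at 0h and 4h lie near the L2H 24h libraries.

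The first comparison asks what changed within 4h of the shift in the H2L arm. The transcript c21329_g1_i1 rose from 9.51 ± 5.2 at 0h to 112 ± 26.9 at 4h (mean ± SD, n = 3), a log2 change of 3.55 with SE 0.43 and adjusted p = 7.09e-05. The transcript c40150_g1_i2 rose from 0.333 ± 0.125 to 14.6 ± 2.31 (log2 change 3.54, SE 0.21, adjusted p = 7.15e-08). Among the transcripts that fell, c31050_g1_i1 went from 87.4 ± 4.45 to 9.52 ± 5.98 (log2 change -3.21, SE 0.32, adjusted p = 1.2e-05), and c47931_g3_i1 went from 13.8 ± 5.8 to 0.667 ± 0.272 (log2 change -3.07, SE 0.31, adjusted p = 1.2e-05). For these 4 transcripts the 3 libraries at 4h did not overlap the 3 at 0h. Limma called 4104 of 34166 transcripts at an adjusted p under 0.05, of which 2218 were higher and 1886 lower at 4h, and 1593 changed at least 2-fold. The share higher, 54.0%, became 47.8% after quantile normalization and 46.4% after upper-quartile scaling, so neither direction held the majority under every scaling. Within libraries 1 and 2, which share a tag set, 7924 were called, 3587 of them in common with the pooled calls and in the same direction. The count was 497 with libraries 1 and 2 averaged, 2673 and 2681 without H2L 0h library 1 or 2, and 2247 and 2396 without H2L 4h library 1 or 2.

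The H2L arm was also compared with its start at 24h. The transcript c50329_g5_i1 rose from 1.29 ± 0.916 to 119 ± 22.5 (log2 change 5.79, SE 0.81, adjusted p = 0.000944), and c48260_g3_i1 from 0.620 ± 0.450 to 64.1 ± 0.510 (log2 change 5.37, SE 0.80, adjusted p = 0.00122). Both had stayed low at 4h, at 0.837 ± 0.305 and 0.433 ± 0.293. The transcript c64590_g1_i1 fell from 186 ± 67.7 to 3.33 ± 2.34 (log2 change -5.57, SE 0.75, adjusted p = 0.000675), and c43486_g1_i1 fell from 59.8 ± 15.6 to 0.963 ± 0.359 (log2 change -4.93, SE 0.30, adjusted p = 1.49e-07). The change of c64590_g1_i1 was -4.97 without H2L 24h library 3. At 4h their log2 changes were -2.39 (adjusted p = 0.0463) and -1.30 (adjusted p = 0.00948), and both calls depended on single libraries. The 4h libraries of c64590_g1_i1 gave 94.8, 67.8 and 4.91, and its change was -1.13 without the third of them (adjusted p = 0.146) and -3.14 without the first (0.0202). It was not called without H2L 0h library 1, 2 or 3 (0.129, 0.128 and 0.0534) or with libraries 1 and 2 averaged (0.152), nor was c43486_g1_i1 without H2L 4h library 1 (0.0589) or with them averaged (0.159). Limma called 2623 transcripts, 873 higher and 1750 lower, against 7317 within libraries 1 and 2 and 24 with those libraries averaged, where c50329_g5_i1, c48260_g3_i1 and c64590_g1_i1 were no longer called (adjusted p = 0.0758, 0.0866 and 0.0633). The share of calls that were higher, 33.3%, became 46.9% after quantile normalization and 50.1% after upper-quartile scaling. The count fell to 915 and 656 without H2L 0h library 1 or 2, and to 1255, 1294 and 1409 without H2L 24h library 1, 2 or 3.

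Many of the early H2L changes were not kept. Between 4h and 24h 4979 transcripts were called, 1961 higher and 3018 lower at 24h. Of the 2218 transcripts higher at 4h than at 0h, 995 were lower at 24h than at 4h, where independent lists would share 196. Of the 1886 that were lower at 4h, 870 were higher at 24h than at 4h, where independent lists would share 108. These comparisons share the 4h libraries, so part of the excess may come from them. The covariance of the changes was -0.176, against -0.0523 in simulated unchanged groups that share libraries in the same way. The transcript c31050_g1_i1 returned from 9.52 ± 5.98 at 4h to 140 ± 35 at 24h, and c21329_g1_i1 stood at 30.2 ± 17.6 at 24h. Its difference from 0h then (log2 change 1.5, adjusted p = 0.045) was 2.14 without H2L 24h library 3 (0.00462), and was not called without any 1 of the other libraries compared (0.0592 to 0.171) or with libraries 1 and 2 averaged (0.321). The overlaps of 995 and 870 were 123 and 135 with those libraries averaged, where independent lists would share 4.25 and 2.36, and 499 and 504 without H2L 4h library 1 and 551 and 573 without library 2. Against 0h, 302 transcripts were higher and 432 lower at both times, where independent lists would share 56.7 and 96.6, and 37 and 30 moved in opposite directions, where they would share 114 and 48.2. Both comparisons use the same 0h libraries, to which part of this excess may belong: the covariance of the changes was 0.111 against 0.0526 in simulated unchanged groups, and r was 0.407 against 0.501. The 302 and 432 were 0 and 1 with libraries 1 and 2 averaged (limma), 85 to 187 and 121 to 275 without library 1 or 2 of any H2L group, and 164 of the first without H2L 24h library 3. The comparison of 24h with 4h gave 8367 calls within libraries 1 and 2 and 891 with those libraries averaged, and the share higher at 24h, 39.4%, became 54.1% and 57.9% after quantile normalization and upper-quartile scaling. Without H2L 4h library 1 or 2 the count was 2836 and 3247, and without H2L 24h library 1 or 2 it was 3227 and 3244.

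**Figure D2:**
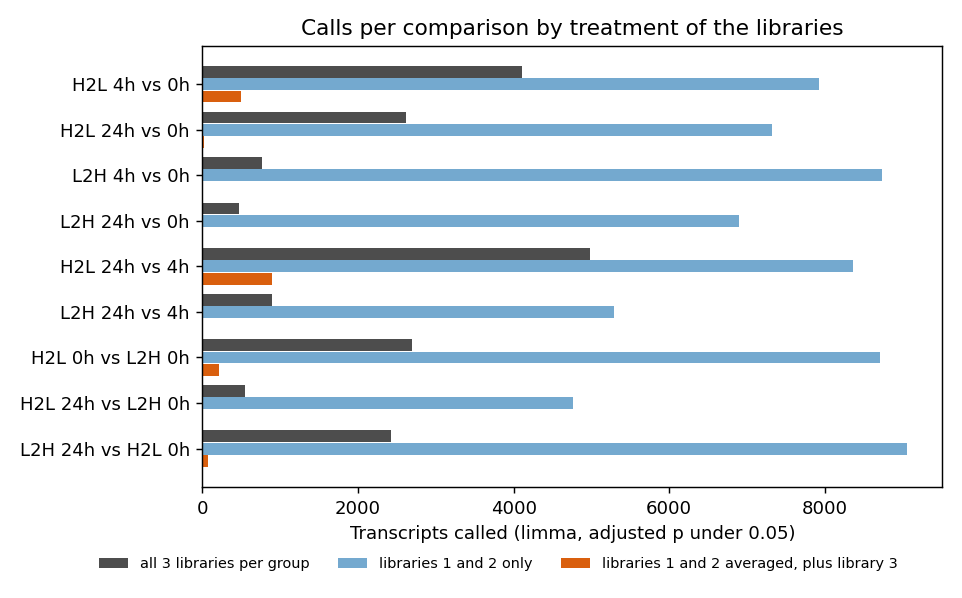
Transcripts called by limma at an adjusted p under 0.05 in each of 9 comparisons, with all 3 libraries per group, with libraries 1 and 2 only, and with libraries 1 and 2 averaged beside library 3. In L2H 4h against 0h the bars stand at 765, 8733 and 0.

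The corresponding question for the L2H arm had an answer that depended on the library series. In libraries 1 and 2 the transcript c30669_g1_i1 went from 0.58 and 0.26 at 0h to 719 and 670 at 4h, but the third library gave 354 at 0h and 375 at 4h. The transcript c45868_g1_i1 went from 1.45 and 0.78 to 224 and 206 in libraries 1 and 2, and the third library gave 137 and 158. The transcript c50329_g5_i1 fell from 154 and 131 to 1.42 and 2.18, and the third library gave 60.5 and 60.1. The transcript c49917_g1_i1 fell from 36.1 and 37.6 to 1.84 and 2.26, and the third library gave 15.3 and 14.8. Over all 3 libraries their log2 changes were 5.99 (SE 1.32, adjusted p = 0.0388), 4.53 (SE 1.05, adjusted p = 0.0407), -3.80 (SE 0.81, adjusted p = 0.0384) and -2.44 (SE 0.59, adjusted p = 0.0431). Each call was lost in 8 of 21 alternatives. The adjusted p was 0.19 to 0.247 without library 1 or 2 at 0h or 4h, 0.312 with only the groups compared in the fit, 0.0704 to 0.0719 without the trend and 0.93 with libraries 1 and 2 averaged. Without L2H 0h library 1, 2 or 3 the change of c30669_g1_i1 was 4.74, 4.58 and 8.65 and that of c45868_g1_i1 3.64, 3.41 and 6.54. Without L2H 4h library 1, 2 or 3 that of c50329_g5_i1 was -2.96, -3.15 and -5.28, and without library 3 that of c49917_g1_i1 was -3.23. These 4 transcripts met the naming rule because their libraries did not overlap between the groups, which includes the narrow gaps of the third library.

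Limma called 765 transcripts between L2H 0h and 4h, 399 higher and 366 lower, against 8733 within libraries 1 and 2. Over those 8733 transcripts the change in the third library had a slope of -0.0512 on the change in libraries 1 and 2 and the same sign in 39.3%. In the H2L arm the corresponding slope was 0.583 and the sign was the same in 80.6% of 7924 transcripts. The pooled L2H count therefore rests on libraries 1 and 2: limma called 0 without L2H 0h library 1 or 2 or without L2H 4h library 1 or 2 (4018, 3982, 4190 and 4368 at an unadjusted p under 0.05), and 3301 and 2645 without the third library at 0h or at 4h. Leaving out library 1 or 2 of a group outside this comparison, which enters only through the pooled spread, left 0 to 4 calls (5992 to 6072 at an unadjusted p under 0.05), so the 765 lie at the edge of the threshold. Limma called 0 with libraries 1 and 2 averaged (1810 at an unadjusted p under 0.05) and 4794 with both the third library at 0h and that at 4h left out, a choice made after seeing the data.

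**Figure D3:**
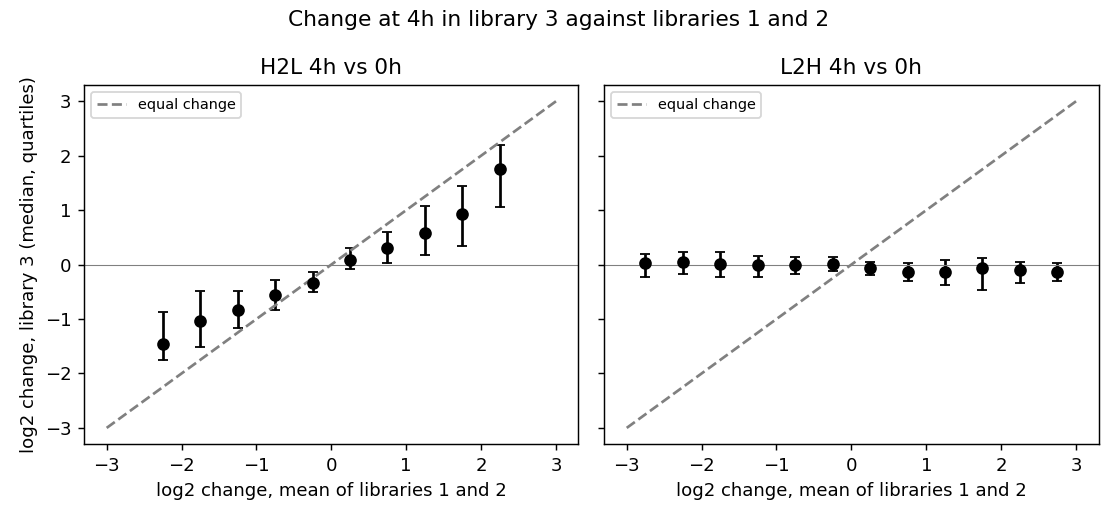
Median and quartiles of the log2 change between 0h and 4h in the third library, in bins of the mean log2 change of libraries 1 and 2, for transcripts called within libraries 1 and 2 of the H2L arm (7924) and the L2H arm (8733); the dashed line marks equal change. The third H2L library followed the other libraries with a slope of 0.583, and the third L2H library with a slope of -0.0512.

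At 24h in the L2H arm the transcripts with the largest rises among those named by the rule were c46349_g2_i1 and c46349_g1_i2, which share the first part of their identifier and may share reads. The transcript c46349_g2_i1 stood at 70.4 ± 98.4 at 0h and 307 ± 36.5 at 24h (log2 change 3.17, SE 0.65, adjusted p = 0.0257), where the 0h libraries gave 14.6, 12.7 and 184. The transcript c46349_g1_i2 stood at 14.3 ± 18.5 and 61.6 ± 5.99 (log2 change 2.77, SE 0.53, adjusted p = 0.0201). Each of these calls was lost in 7 of 21 alternatives, among them leaving out L2H 0h library 1 or 2 (adjusted p = 0.161 and 0.152 for c46349_g2_i1, 0.135 and 0.125 for c46349_g1_i2) or any L2H 24h library (0.0916, 0.0834 and 0.0653 for c46349_g2_i1, 0.0698, 0.0713 and 0.06 for c46349_g1_i2). The highest adjusted p over their alternatives was 0.643 and 0.593. These losses are counted at an adjusted p of 0.05, and neither call would stand under 0.01. Without L2H 0h library 3 their changes were 4.39 and 3.78, and without library 2 that of c46349_g2_i1 was 2.51. The transcript c50329_g5_i1 fell from 115 ± 48.9 to 1.68 ± 1.29 (log2 change -5.43, SE 0.81, adjusted p = 0.00528), and c48260_g3_i1 fell from 73.8 ± 36.5 to 1.51 ± 1.15 (log2 change -4.83, SE 0.80, adjusted p = 0.00981). The call of c50329_g5_i1 was lost with only the groups compared in the fit (adjusted p = 0.0589) and with libraries 1 and 2 averaged (0.384). The call of c48260_g3_i1 was lost without L2H 0h library 1 or 2 (adjusted p = 0.0766 and 0.0709) and without L2H 24h library 1 (0.0517), and reached 0.521 over its alternatives. Limma called 474 transcripts, 294 higher and 180 lower, against 6892 within libraries 1 and 2 and 0 with those libraries averaged (2218 at an unadjusted p under 0.05). Over those 6892 transcripts the change in the third library had a slope of 0.172 on that in libraries 1 and 2 and the same sign in 57.8%. This change starts from the third L2H library at 0h, which stood apart, so the slope does not show that the third library at 24h differed. At 24h its r with libraries 1 and 2 was 0.956 and 0.962. The share higher, 62.0%, became 51.6% after quantile normalization and 37.3% after upper-quartile scaling. The count was 31, 27 and 2102 without L2H 0h library 1, 2 or 3, and 66, 79 and 191 without L2H 24h library 1, 2 or 3. Through the pooled spread it was 299 and 293 without H2L 0h library 1 or 2, 275 without H2L 4h library 1 and 286 without H2L 24h library 2. It was 2727 with the third L2H libraries at 0h and 4h left out.

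From 4h to 24h in the L2H arm 894 transcripts were called, 641 higher and 253 lower at 24h. Of the 399 transcripts higher at 4h than at 0h, 95 were lower at 24h than at 4h, and of the 366 lower at 4h, 81 were higher at 24h. Independent lists would share 2.95 and 6.87, and part of the excess may come from the shared 4h libraries. The covariance of these changes was -0.108 against -0.0521 in simulated unchanged groups, and r was -0.538 against -0.499. The 95 and 81 were 0 and 0 with libraries 1 and 2 averaged (limma) and 0 to 3 without library 1 or 2 of any group. They were 368 and 199 without L2H 0h library 3 and 381 and 613 without L2H 4h library 3, and the first was 63 without L2H 24h library 3. The transcript c30669_g1_i1 stood at 588 ± 186 at 4h and 31.3 ± 6.33 at 24h, a difference that was not called (log2 difference -4.15, SE 1.32, adjusted p = 0.11). The comparison gave 5297 calls within libraries 1 and 2, 1 with those libraries averaged, and 2499 with the third L2H libraries at 0h and 4h left out. The share higher, 71.7%, became 60.2% and 51.5% after quantile normalization and upper-quartile scaling, and the count was 109, 150 and 1871 without L2H 4h library 1, 2 or 3 and 226 and 195 without L2H 24h library 1 or 2.

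The arms were also compared at their start. The transcript c64590_g1_i1 stood at 186 ± 67.7 in H2L at 0h and was listed at 0 in every L2H library at 0h (log2 difference 7.47 with the pseudocount, SE 0.75, adjusted p = 1.28e-05). The transcript c9269_g1_i1 stood at 124 ± 43.6 in H2L and 0.433 ± 0.50 in L2H (log2 difference 6.43, SE 0.34, adjusted p = 6.5e-09). The transcripts c50329_g5_i1 and c48260_g3_i1 were lower in H2L, at 1.29 ± 0.916 against 115 ± 48.9 (log2 difference -5.66, SE 0.81, adjusted p = 0.000423) and at 0.620 ± 0.450 against 73.8 ± 36.5 (log2 difference -5.41, SE 0.80, adjusted p = 0.000518). Limma called 2689 transcripts, 1550 higher and 1139 lower in H2L, against 8710 within libraries 1 and 2 and 215 with those libraries averaged, where c48260_g3_i1 was no longer called (adjusted p = 0.0517). The count was 1177 and 1052 without H2L 0h library 1 or 2, and 1368 and 1310 without L2H 0h library 1 or 2.

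**Figure D4:**
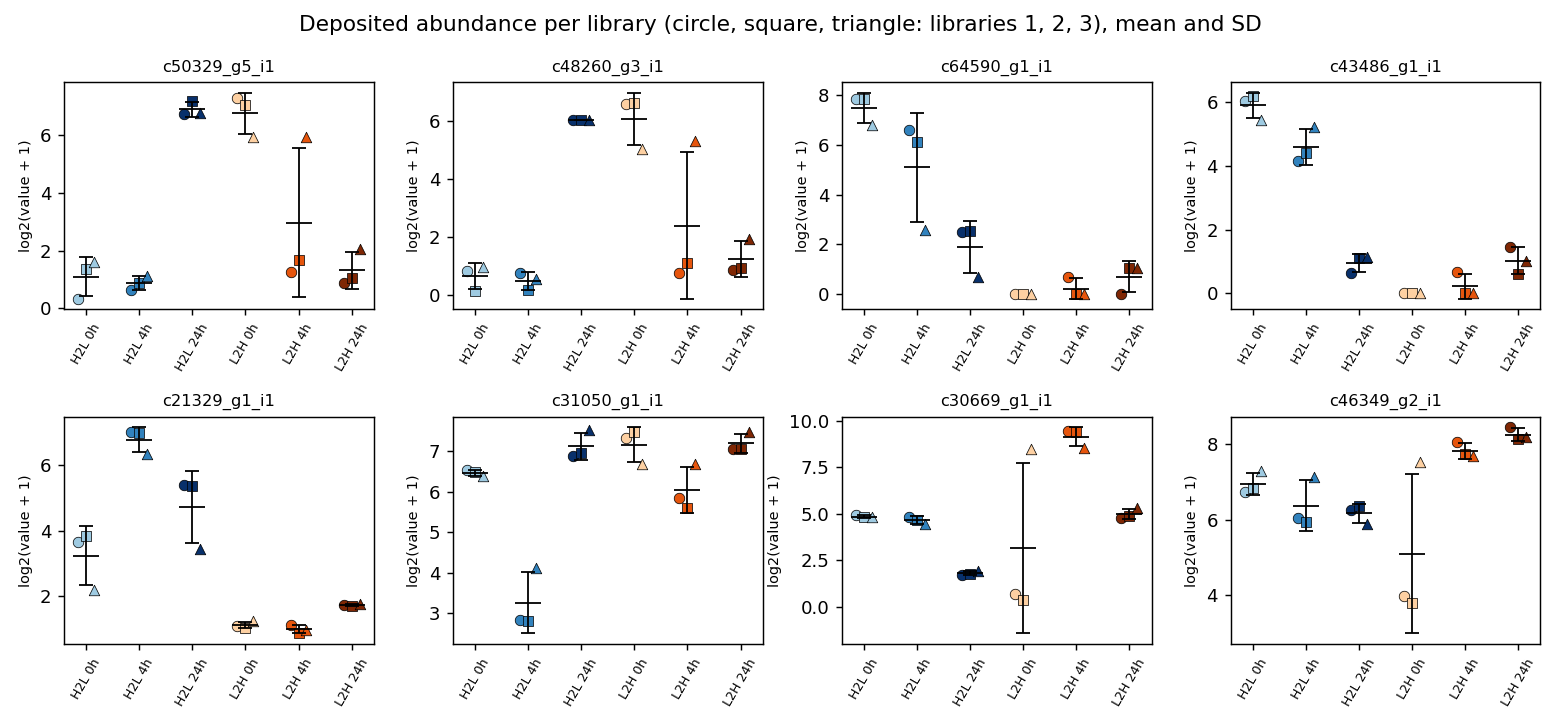
Deposited abundance as log2(value + 1) of 8 named transcripts in each library, with the mean and SD of each group of 3. The transcripts c50329_g5_i1 and c48260_g3_i1 were high at H2L 24h and L2H 0h and low at H2L 0h and L2H 24h, and the third L2H library at 4h (triangle) stood near the 0h values.

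The end of each arm was compared with the start of the other. At 24h the transcript c50329_g5_i1 stood at 119 ± 22.5 in H2L, close to its 115 ± 48.9 in L2H at 0h, and at 1.68 ± 1.29 in L2H, close to its 1.29 ± 0.916 in H2L at 0h. The transcripts named for a fall in H2L by 24h or as higher in H2L at 0h were far from that start in L2H at 24h. There c64590_g1_i1 stood at 0.730 ± 0.632 against 186 ± 67.7 (limma adjusted p = 6.13e-05), c9269_g1_i1 at 0.1 ± 0.173 against 124 ± 43.6 (8.61e-09), and c43486_g1_i1 at 1.09 ± 0.598 against 59.8 ± 15.6 (7.46e-08). None of the transcripts named for a change in L2H was called between L2H 24h and H2L 0h (adjusted p = 0.233 to 0.973). The transcript c43486_g1_i1, at 0.963 ± 0.359 in H2L at 24h, was listed at 0 in the 3 L2H libraries at 0h. H2L 24h and L2H 0h differed in 549 transcripts, 283 of them higher in H2L, and L2H 24h and H2L 0h in 2420, 1358 of them higher in L2H. The libraries were placed on the line between the starting states, with the starting libraries in each product taken from different tag sets. A placed library can still share its tag set with a starting library in the product, which may move its position. By 24h H2L had covered 0.746 ± 0.169 of the distance and L2H 0.166 ± 0.148 (n = 3 each). The exact permutation p for this difference, two-sided, was 0.1, the smallest that 3 against 3 can give. The L2H libraries gave 0.054, 0.11 and 0.334, and without the third the mean was 0.082; the third L2H library at 0h, which stood apart, enters the line itself. At 4h the distances covered were -0.0282, 0.104 and 0.0138 in the H2L libraries and -0.127 ± 0.0252 in L2H. Of the 1550 transcripts higher in H2L at the start, 684 fell in H2L by 24h, and of the 1139 lower at the start, 392 rose, where independent lists would share 79.4 and 29.1. In L2H, 143 of the 1550 rose and 101 of the 1139 fell by 24h, where independent lists would share 13.3 and 6. Part of each excess may come from the shared 0h libraries. The covariance of the starting difference and the 24h change was -0.183 in H2L against -0.0524 in simulated unchanged groups, and 0.114 in L2H against 0.0523, with r of 0.485 against 0.5 in L2H. The 684 and 392 were 18 and 1 with libraries 1 and 2 averaged. They were 237 and 126, 186 and 94, and 1041 and 613 without H2L 0h library 1, 2 or 3, 439 to 450 and 200 to 211 without any H2L 24h library, and 386 and 217 or 391 and 222 without L2H 0h library 1 or 2. The 143 and 101 were 0 and 0 with libraries 1 and 2 averaged (limma), 8 to 28 and 13 to 30 without library 1 or 2 of L2H 0h or L2H 24h, 60 and 41 without L2H 24h library 3, and 590 and 350 without L2H 0h library 3. They were 75 to 77 and 52 to 55 without H2L 0h library 1 or 2, 88 and 63 without H2L 4h library 1, and 92 and 66 without H2L 24h library 2.

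Within libraries 1 and 2 these end comparisons gave 4761 and 9061 calls, and with those libraries averaged 5 and 69. The third library followed libraries 1 and 2 with a slope of 0.177 in the first (same sign in 52.9%) and 0.337 in the second (68.5%), and of 0.307 between the arms at 0h (63.3%). For H2L 24h against L2H 0h the count was 161 and 192 without H2L 24h library 1 or 2 and 232 and 190 without L2H 0h library 1 or 2. For L2H 24h against H2L 0h it was 800 and 538 without H2L 0h library 1 or 2 and 695 and 828 without L2H 24h library 1 or 2. Upper-quartile scaling moved the share of higher calls from 51.5% to 62.8% in the first and from 56.1% to 42.3% in the second.

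Whether the arms changed differently was tested directly. At 4h the changes of 3484 transcripts differed between the arms, among them c40150_g1_i2, which rose in H2L and stood at 0.347 ± 0.127 and 0.0667 ± 0.115 in L2H at 0h and 4h. At 24h 2200 differed, among them c50329_g5_i1 and c48260_g3_i1, which rose in H2L and fell in L2H. Transcripts called in both arms at 24h went mostly opposite ways: 43 rose in H2L and fell in L2H and 53 did the reverse, 96 in all, while 14 rose and 10 fell in both. Independent lists would share 4.6, 15.1, 7.51 and 9.22. At 4h 48 and 42 went opposite ways, 90 in all, and 8 and 20 the same way, where independent lists would share 23.8, 22.0, 25.9 and 20.2. Across transcripts the 24h changes of the arms had r = -0.160 and the 4h changes r = -0.0985, and the arms share no libraries. Within libraries 1 and 2 the arm difference was called for 8996 transcripts at 4h and 7260 at 24h, with 2005 and 1758 called in both arms in opposite directions. With those libraries averaged these counts were 14, 43, 0 and 0. With the third L2H libraries at 0h and 4h left out they were 5854, 4068, 799 and 600. Leaving out library 1 or 2 gave 2219 and 2280 arm differences at 4h for H2L 4h, 1845 and 1786 for L2H 0h, and 1983 and 2080 for L2H 4h. At 24h it gave 1147 and 1098 for H2L 0h, 1059 and 1118 for L2H 0h, and 1323 for L2H 24h library 2, while leaving out the third library gave 1417 for H2L 24h and 3434 for L2H 0h. The opposite calls at 4h were 0 without library 1 or 2 of H2L 0h, H2L 4h, L2H 0h or L2H 4h, no more than 3 without library 1 or 2 of a 24h group, and 518 and 317 without the third library of L2H 0h or L2H 4h. Those at 24h were 39 and 33 without library 1 or 2 of H2L 0h, 53, 47 and 59 without library 1, 2 or 3 of H2L 24h, 16, 16 and 411 of L2H 0h, and 27, 27 and 53 of L2H 24h. The share of arm differences at 24h that were positive, 34.8%, became 48.7% after quantile normalization and 57.4% after upper-quartile scaling.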

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

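The tests of the third L2H libraries and of the H2L 4h libraries, and all counts over other splits of the samples, were written down after the values they measure had been seen. Over all tested transcripts the 4h change differed between the arms in 3484 and the 24h change in 2200. Single values are listed for transcripts already named for a change from 0h, where the arm difference had an adjusted p under 0.05. Naming picked large changes in these same libraries, which makes an arm difference likely, so these values are no separate support. At 4h c50329_g5_i1 and c49917_g1_i1 were also named but did not reach it (limma adjusted p = 0.0589 and 0.159). At 4h the log2 change in H2L minus that in L2H was 3.69 for c21329_g1_i1 (limma adjusted p = 0.00208), 3.88 for c40150_g1_i2 (3.92e-06), -2.09 for c31050_g1_i1 (0.00977) and -3.03 for c47931_g3_i1 (0.000877). It was -6.19 for c30669_g1_i1 (0.0436) and -4.82 for c45868_g1_i1 (0.0491), both resting on L2H changes whose calls were lost in 8 of 21 alternatives. At 24h it was 11.23 for c50329_g5_i1 (5.74e-05), 10.20 for c48260_g3_i1 (0.000109), -6.28 for c64590_g1_i1 (0.00305) and -5.96 for c43486_g1_i1 (1.78e-06). It was -3.96 for c46349_g2_i1 (0.0172) and -3.78 for c46349_g1_i2 (0.00838), which share the first part of their identifier. Their calls in L2H at 24h were each lost in 7 of 21 alternatives.

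The arm difference at 4h was reached by 1 of 100 drawn splits of the libraries within the arms, the real one (3484, highest other 2783), and at 24h by 1 of 100 (2200, highest other 1327). These splits exchange 0h with the later time, so they remove the time change itself and cannot test a difference between the arms. In both cases the highest other split kept the true H2L times. For both, chance assignment of libraries to times is excluded at the level of 0.05 only if the 3 libraries of a group are separate samples. Libraries 1 and 2 share a tag set, and with them averaged as 1 sample the counts are 14 and 43, and the splits are then too few to exclude chance. The opposite calls at 24h were reached by 1 of 100 (96, highest other 1), under the same condition. Those at 4h were reached by 2 of 100. The other one kept the times of the third L2H libraries, exchanged those of L2H libraries 1 and 2, and gave 147. These 147 are opposite to H2L only in that reversed order, so they are not comparable with the real 90. That split follows the tag set and points to a structure of the samples. Within libraries 1 and 2 the count is 2005.

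Each comparison of 3 libraries with 3 has 10 splits, too few for a share under 0.05. The real split alone (1 of 10) reached its count in H2L 4h against 0h (4104, highest other 1), H2L 24h against 0h (2623, highest other 0), L2H 24h against 0h (474, highest other 1), H2L 24h against 4h (4979, highest other 1) and L2H 24h against 4h (894, highest other 0). The same held between the arms for H2L 0h and L2H 0h (2689, highest other 105), H2L 24h and L2H 0h (549, highest other 5), and L2H 24h and H2L 0h (2420, highest other 0). In L2H 4h against 0h 2 of 10 splits did so, since the split that exchanges the third libraries called 2155 against the real 765. Within libraries 1 and 2 of that comparison 8733 were called.

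The change between 0h and 4h of the L2H arm is missing from the third libraries. An exchange of their labels would make their change run against that of libraries 1 and 2, but the slope was -0.0512, and exchanging them would turn it only to a value near 0; the 2155 calls after an exchange arise although nearly the same profile stands on both sides. The SD of the log2 ratio between them was 0.209 over 5668 transcripts, as between L2H 0h libraries 1 and 2 (0.209), against 0.842 between L2H 0h and 4h in library 1. A weaker or slower response from the same start is argued against by the third 0h library, which lay at 0.583 of the way from 0h to 4h. A blend of 0h and 4h RNA or cells in both libraries remains a candidate explanation: the median share of the distance covered was 0.546 for 98 rising and 0.546 for 81 falling transcripts at 0h, and 0.527 and 0.529 at 4h, 0.019 apart at most, whereas L2H 24h library 1 gave 0.203 and 0.708. A library series that had reached such a state by culture, under its own tag set, stays open and untested. Close shares were also seen outside the L2H arm: the third H2L library at 4h gave 0.851 for 16 rising and 0.848 for 14 falling transcripts on the H2L distance.

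In the H2L arm fewer transcripts were listed at 0 at 4h than at 0h in 3 of 3 library series (3969, 3968 and 5479 against 4813, 4815 and 6045; exact permutation p = 0.3 over all 3 against 3). Deeper sequencing would lower the value of 1 read at 4h. The ratio of that value, 4h to 0h, was 1.01 ± 0.0249 (SD, n = 3), but the rows used keep it near 1. Deeper sequencing therefore stays open. A smaller share of signal in the 100 most abundant transcripts cannot be told apart from its spread, since that share differed by 0.93 ± 3.44 percentage points between 4h and 0h and was lower in 2 of 3 series. Broader transcription at 4h may also account for it, which was not tested.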

How the results depend on the processing

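Averaging libraries 1 and 2, leaving out the third L2H libraries and leaving out libraries outside a comparison were chosen after seeing the data. No named transcript changed direction under any alternative run: of 412 values for 20 named results, 355 kept an adjusted p under 0.05 and 57 lost it. The 355 include the settings with a 2-fold minimum and with an adjusted p under 0.01, where the values are those of the main fit. The losses lay mostly in the L2H arm; averaging libraries 1 and 2 lost 12 of 20 and kept 8. Quantile normalization, upper-quartile scaling, no filter and pseudocounts of 0.1 and 5 kept all 13 counts within 1.5 times. The absolute depth is unknown, so the smallest detectable change at low abundance is not given. Where no cause is named below, the cause was not tested. The lists of gene families gave no values, since 0 identifiers matched names.

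Counts are given in this order: H2L 4h and 24h against 0h; L2H 4h and 24h against 0h; 24h against 4h in H2L and L2H; H2L 0h against L2H 0h; H2L 24h against L2H 0h; L2H 24h against H2L 0h; arm difference at 4h and 24h; opposite calls at 4h and 24h. With libraries 1 and 2 only they were 7924, 7317, 8733, 6892, 8367, 5297, 8710, 4761, 9061, 8996, 7260, 2005 and 1758. With array weights they were 8665, 7492, 7175, 4574, 9470, 4230, 7909, 2916, 8251, 8975, 6766, 1465 and 1002. At an adjusted p under 0.01 they were 1675, 625, 0, 47, 2109, 138, 962, 162, 508, 992, 566, 0 and 16. With libraries 1 and 2 averaged, which leaves 2 samples per group, they were 497, 24, 0, 0, 891, 1, 215, 5, 69, 14, 43, 0 and 0. With a 2-fold minimum the 9 comparisons gave 1593, 1007, 436, 256, 2092, 490, 1218, 353 and 912, and the opposite calls 28 and 55.

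With only the groups compared in the fit, which lowers the degrees of freedom, H2L 4h and 24h against 0h gave 2230 and 1540, L2H 4h and 24h against 0h 0 and 0 (limma, each with 5018 at an unadjusted p under 0.05), and L2H 24h against 4h 57. The comparisons between arms gave 974, 43 and 561, and the opposite calls at 4h 0. A minimum value of 10, which tests fewer transcripts, gave 1392 for L2H 4h against 0h, 357 for H2L 24h against L2H 0h and 175 opposite calls at 4h. Without the trend L2H 4h against 0h gave 1 and the opposite calls at 4h 0. Without the third L2H libraries at 0h and 4h, L2H 4h and 24h against 0h gave 4794 and 2727, L2H 24h against 4h 2499, the arm differences 5854 and 4068, and the opposite calls 799 and 600.

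Same-numbered libraries did not deviate together throughout (for libraries 1, 2 and 3 r was 0.0944 to 0.111, 0.0726 to 0.0882 and 0.234 to 0.259 in H2L, and -0.0453 to 0.0821, -0.0438 to 0.0609 and -0.182 to 0.152 in L2H, and 11 of 18 libraries correlated best with their own number). All values in H2L were positive, but not every pair exceeded 0.1, so the numbers were not taken to pair the samples. With the library number within the arm as a replicate block, L2H 4h against 0h gave 0 (limma, 6935 at an unadjusted p under 0.05). L2H 24h against 0h gave 792 with this block, and the opposite calls were 0 at 4h and 151 at 24h. Each of the 4 calls named for L2H 4h against 0h was lost there (limma adjusted p = 0.0522). With the set of tags as the block, the comparisons between arms gave 5361, 2156 and 4377.

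Leaving out 1 library of the groups compared at a time gave 2247 to 4319 for H2L 4h and 656 to 3335 for H2L 24h against 0h, 0 to 3301 for L2H 4h and 27 to 2102 for L2H 24h against 0h, 2836 to 4812 for 24h against 4h in H2L and 109 to 1871 in L2H. It gave 1052 to 3446 for H2L 0h against L2H 0h, 161 to 689 for H2L 24h against L2H 0h and 538 to 3317 for L2H 24h against H2L 0h. The arm differences ranged over 1786 to 4871 at 4h and 1059 to 3434 at 24h, and the opposite calls over 0 to 518 and 16 to 411. The lowest arm difference at 24h came without L2H 0h library 1 and the highest without L2H 0h library 3. Without a library of a group outside the comparison, the count reached 4482 for H2L 4h against 0h and 5427 for H2L 24h against 4h, above these ranges.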

Other observations

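The transcripts in this part were chosen after their values were seen. The most abundant transcript on average, c46710_g2_i7, stood at 11790 ± 1211, 11590 ± 438 and 19470 ± 2503 in H2L at 0h, 4h and 24h, and at 20920 ± 2735, 11980 ± 5804 and 16820 ± 3815 in L2H. No change from 0h was called (adjusted p = 0.983 and 0.208 at 4h and 24h in H2L, 0.162 and 0.688 in L2H). In L2H libraries 1 and 2, however, c46710_g2_i7 went from 23546 and 21133 at 0h to 8657 and 8610 at 4h. The third L2H library gave 18087 at 0h and 18686 at 4h. The transcripts c66899_g1_i1 and c30263_g2_i1 were abundant in the H2L arm: c66899_g1_i1 stood at 3608 ± 658, 7120 ± 1680 and 1158 ± 169 at 0h, 4h and 24h, against 97.2 ± 23.0, 109 ± 38.5 and 165 ± 6.07 in L2H. c30263_g2_i1 stood at 2214 ± 162, 3593 ± 1130 and 550 ± 61 in H2L, and at 101 ± 42.6, 200 ± 62.3 and 173 ± 50.3 in L2H. At 0h the arms differed by log2 5.21 (adjusted p = 1.58e-09) and 4.51 (5.95e-08). The falls from 0h to 24h in H2L, -1.63 (0.00119) and -2.01 (0.00109), were not called with libraries 1 and 2 averaged (0.0866 and 0.0904). The rise at 4h was not called for c30263_g2_i1 (0.156), and for c66899_g1_i1 (0.0149) it was not called without the third library of H2L 0h or 4h (0.0603 and 0.0545) or with libraries 1 and 2 averaged (0.0906).

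In libraries 1 and 2 of the H2L arm 17 transcripts were over 10-fold higher than in each other library series, in means over all times. The largest were c46786_g1_i2, with a mean of 96.8 there against 5.66 in the third H2L libraries, 8.03 in L2H libraries 1 and 2 and 7.75 in the third L2H libraries, and c48463_g3_i1, with 82.6 against 4.20, 0.752 and 0.600. At 0h alone c46786_g1_i2 gave 75.6 and 80.54 against 16.45 and 15.89 in L2H libraries 1 and 2. The remaining transcripts were low, with means of 1.01 to 6.26 against at most 0.463. The same search gave 1 transcript for the third H2L libraries and 0 for each L2H series.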
